A study of Mus musculus with 6 samples.

How the data were processed

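Gene expression was measured on Affymetrix mouse arrays in 6 samples of 3 groups with 2 samples each. The groups, per the labels, were embryonic stem cells (ESC) kept without feeder cells in 2i and LIF, epiblast-like cells (EpiLC) on day 2 of induction with activin and bFGF, and primordial germ cell-like cells (PGCLC) on day 6 of induction from EpiLC with BMP4, BMP8a, SCF, EGF and LIF. All cells were male, of the C57BL/6 strain, and carried fluorescent reporters driven from Blimp1 (Prdm1) and stella (Dppa3). Per the labels' protocols, total RNA was purified on RNeasy columns, cDNA was amplified by 22 PCR cycles from 5 ng of total RNA, an amount given as that of 500 cells, and biotin-labelled cRNA was hybridised. The labels name no sorting of the cells. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

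The authors made the values from earlier arrays with dChip, per the series design text. The dChip version, the array normalization, the expression model and the background setting are not given in the sources used here. The deposited values were used as log2 expression values. The log base is not written in the deposited table and was inferred from the values, which ran from 0 to 14.05. Read as natural logarithms, the highest values would lie above the largest signal that an Affymetrix scanner records. Every difference and fold below rests on that reading. Between 2.18% and 2.41% of probe sets per array stood at exactly 0, a floor at which values have no order, and no detection calls were used here. For 126, 197 and 167 of the called genes, in the order of the comparisons, the lower group's mean lay below the lower quartile of all probe sets on its arrays. Their differences are given as bounds, with lower values raised to each array's quartile, a limit chosen after the values were seen that is no measured background. Another deposited table, which had been planned as the source, names its 8 columns for samples other than those analysed here, and these 8 columns were not used. It had been read for first fits and was then set aside, and none of the results given here comes from it. Because the values were already on a log scale, they entered the tests as deposited, without the added constant that had been planned for linear values.

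Each of 45101 probe sets was named through the platform annotation supplied with the values. Of these, 34958 had 1 gene symbol, 932 had several symbols and 9211 were not listed with a gene, and only probe sets with 1 symbol were named. Entrez gene numbers of 34754 probe sets matched the mouse RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table was used for names and for chromosome membership alone. The 64 Affymetrix control probe sets were left out of the tests. A gene with several probe sets, as for 9010 genes, was represented by the probe set with the highest mean over the 6 arrays, which gave 18193 genes. No filter on low values was applied.

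Groups were compared with limma 3.58.1 in R 4.3.3 by a linear model with 1 coefficient per group over all 6 arrays, which left 3 residual degrees of freedom. Variances were moderated with a mean-variance trend, with 3.29 prior degrees of freedom. The moderated test was two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison. A gene was called higher or lower at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Differences are given with the standard error (SE) of that model, and group levels with the standard deviation (SD) of the 2 arrays. The number of arrays limits the precision of every value.

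Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 24 lists of each comparison. The lists were naive pluripotency, core pluripotency, formative epiblast, germ cell specification, later germline and meiosis, primitive streak and mesoderm, Hox genes, endoderm, neuroectoderm, trophoblast, blood and endothelium, the 2-cell-like state, DNA methylation and demethylation, histone H3 lysine 9 and 27 methylation, BMP targets, activin and Nodal targets, FGF and ERK targets, cell cycle, cell cycle inhibitors, glycolysis, oxidative phosphorylation, imprinted genes, stress and immediate early genes, and epithelial and mesenchymal genes. Camera was repeated with the correlation estimated from the residuals. That repeat uses only the 3 residual degrees of freedom, at which few lists can pass. In addition, limma's fry was run. Fry tests whether a list's own genes move, on balance, one way, without comparing them with other genes. Members of a list with no named probe set, Nanos3 and T among them, were not analysed here.

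The test, the groups in the fit, the lists, most of the other settings tried and the rule for named genes were fixed before the data were examined. For each comparison the rule took the 8 called genes with the largest positive and the 8 with the largest negative difference among those that reached a linear level of 200 (7.64 on the log2 scale) in the higher group without overlap of arrays. It also took up to 4 called members of each list with the largest differences, or the 2 largest where none was called. It added these marker genes in every comparison (Prdm1, Dppa3, Tfap2c, Prdm14, Nanos3, Fgf5, Dnmt3b, Otx2, Klf4, Zfp42, Nanog, Pou5f1 and Sox2) and the 5 genes with the largest smaller step in each pattern of calls over both steps. Other genes named in the text were chosen after their values were seen, and are said to be so where they appear.

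The groups share the replicate numbers 1 and 2 in the labels, which do not say what a number stands for. Whether the numbers pair the samples was therefore checked in the data, before the calls of the fits were compared. Deviations from the group means of samples with the same number correlated across all genes at 0.16 (ESC and EpiLC), 0.31 (ESC and PGCLC) and 0.20 (EpiLC and PGCLC). Over 8380 genes with a mean of at least 7 the values were 0.44, 0.84 and 0.50, and the third principal component (13.6% of the variance) separated replicate 1 from replicate 2 in all 3 groups. With 3 such differences, signs match by chance in 1 of 4 cases. The numbers were treated as pairing the samples on this basis, and the fit with the replicate number as a block was an alternative whose value is printed where it changed a call.

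Alternatives to these choices were a filter on genes with a mean under a linear level of 100 (6.64 on the log2 scale), the mean of a gene's probe sets, every probe set tested by itself, quantile normalization on top of the deposited values, median centring, no mean-variance trend, only the groups compared, the replicate block, no minimum difference, a minimum of 2, and leaving out each array in turn. After leaving out an array, its group had a lone sample that was assumed to vary like the other groups. Such a fit also has fewer residual degrees of freedom and no replicate block, so replicate number and group are mixed in it. Calls can therefore be lost whichever array is left out. Compression of low values with an added constant of 32, and the filter together with the block, were added after the data were seen. A change of sign between values that were called in neither setting was counted as no change.

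The fit was tested on simulated data for EpiLC against ESC, in 20 draws over 18193 genes of which 200 were changed. It recovered 24.3% of genes changed by 1 on the log2 scale, 93.2% at 2, 99.0% at 3 and 99.9% at 4, with 7% false calls among those made. The changed genes were drawn only from those with an ESC level of at least 7, so recovery of dimmer genes was not tested. A changed list, made only of raised genes, was called in 100% of draws and an unchanged one in 0%, in camera at an unadjusted p under 0.05. The changed list was longer than any real list and all its genes rose by 1 to 4, so its call was nearly assured. The simulated noise was independent between genes, unlike the replicate differences shared between groups in the data. These rates and that of false calls may therefore not carry over to the real genes and lists. The correlation and covariance of the steps were set against 100 simulations of unchanged groups that shared the EpiLC arrays. Figures were drawn with matplotlib 3.10.9 and tables prepared with pandas 2.3.3 under Python 3.11.15.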

Results

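The data held 6 arrays that follow mouse cells in culture from embryonic stem cells (ESC) through epiblast-like cells (EpiLC) to primordial germ cell-like cells (PGCLC), with 2 arrays per group. The labels describe a series of induced cell states, and the question taken from them was how gene expression changed at each step of that path. Median log2 values of the arrays lay between 5.00 and 5.08. Correlations across genes, each represented by its brightest probe set, were 0.976 between the ESC arrays, 0.967 between the EpiLC arrays and 0.972 between the PGCLC arrays. They ranged from 0.918 to 0.941 between arrays of different groups. The first and second principal components held 39.9% and 32% of the variance. The difference between the 3' and 5' control probe sets, a sign of RNA length, was 0.72 to 1.06 for Gapdh in the ESC and EpiLC arrays and 1.44 and 0.96 in the PGCLC arrays, and 2.60 to 3.51 for Actb over all arrays. Unless stated otherwise, values below are log2 differences between means of 2 arrays ± SE, with p adjusted over all genes tested in limma. No value was tested against background, and means above the lower quartile of an array may also lie near background. For a called gene whose lower group had a mean below that quartile of its arrays, the difference is given as at least a value, measured from that quartile.

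From ESC to EpiLC, genes of the post-implantation epiblast rose and genes of the naive state fell. Fgf5, a growth factor gene that marks the post-implantation epiblast, rose by at least 6.13 (adjusted p = 0.00053), from 2.40 ± 0.15 in ESC to 9.48 ± 0.47 in EpiLC (SD, n = 2 each). Pou3f1, which encodes the transcription factor OCT6, rose by 6.63 ± 0.30, and the de novo DNA methyltransferase genes Dnmt3a and Dnmt3b rose by 3.99 ± 0.17 and 2.52 ± 0.26. In the other direction, Prdm14, a regulator of naive pluripotency and of germ cell fate, fell by at least 6.54 (adjusted p = 0.00053), Klf4 fell by 5.18 ± 0.29 and Nanog fell by 3.06 ± 0.21. Pou5f1, which encodes the core pluripotency factor OCT4, stood at 12.86 ± 0.01 in ESC and 12.80 ± 0.12 in EpiLC (SD, n = 2 each), a difference of -0.07 ± 0.15 with an adjusted p of 0.84.

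In total 722 genes were called higher and 821 lower in EpiLC than in ESC, 8.5% of the 18193 genes tested. Among genes bright in the higher group and without overlap of arrays, those the rule took by the difference of deposited values also included Tmem54 (higher by at least 6.41), the membrane carbonic anhydrase gene Car4 (6.79), the myosin light chain gene Myl9 (6.08), the immediate early gene Egr1 (6.02) and the G protein regulator gene Rgs2 (at least 4.35). Besides Prdm14, the decreases taken by the same rule included those of the junction protein gene Jam2 (-7.58), Crxos (lower by at least 6.52), the naive state factor gene Tfcp2l1 (-6.05), the WNT target gene Sp5 (-6.03), Lrrc34 (-5.95) and the imprinted gene Plagl1 (-5.93). All 1543 called genes had the same sign within replicate 1 and within replicate 2, which the rule for a call nearly ensures. The number of calls fell whichever array was left out. It was 158 higher and 189 lower without ESC replicate 1, 156 and 181 without ESC replicate 2, 255 and 425 without EpiLC replicate 1, and 386 and 527 without EpiLC replicate 2, and the filter on low values left 446 higher.

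**Figure D1:**
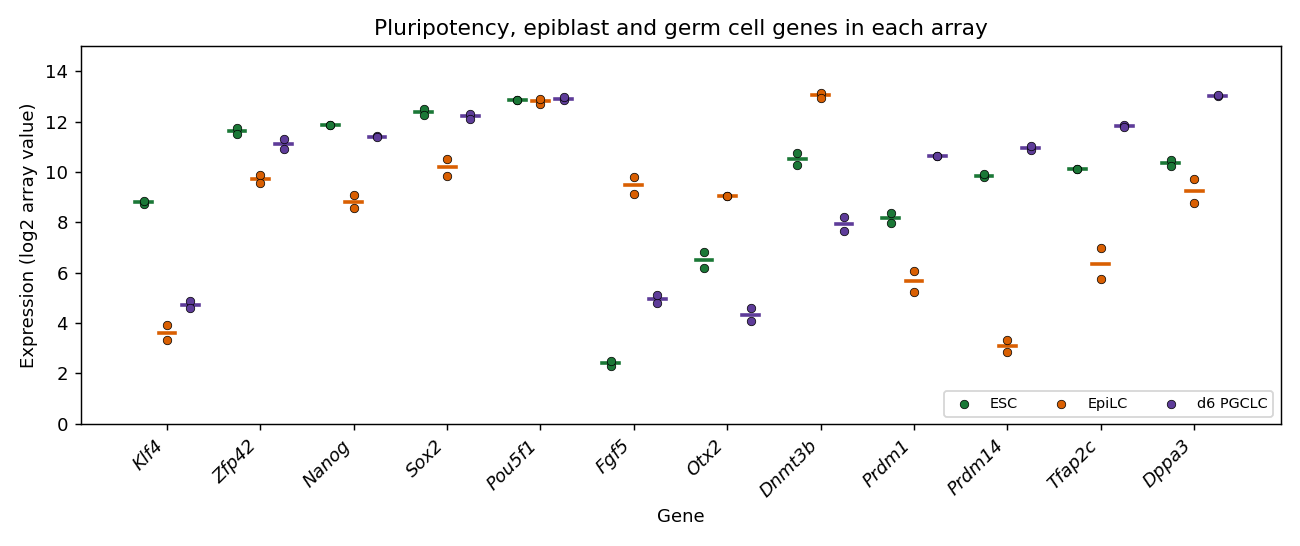
Log2 array values (vertical axis) of 12 pluripotency, epiblast and germ cell genes (horizontal axis), with 1 point per array, a bar at the mean of each group and colours for ESC, EpiLC and PGCLC. Pou5f1 is level near 12.8, Fgf5 peaks in EpiLC at 9.48, and Prdm14 falls to 3.08 in EpiLC and stands at 10.96 in PGCLC.

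The naive pluripotency list moved down as a set. Of its 20 measured members 14 fell and 0 rose, and 16 fell when adjusted over the list alone (camera adjusted p = 1.6e-16, adjusted p = 0.051 with an estimated correlation). Tfcp2l1, Nr5a2 (-5.79), Tcl1 (-5.80) and Prdm14 fell the most. The formative epiblast list moved the other way, with 13 of 21 members higher and 1 lower, or 14 and 1 adjusted over the list alone (camera adjusted p = 8.9e-12, adjusted p = 0.051 with an estimated correlation). Besides Fgf5, Pou3f1 and Dnmt3a, the kinase gene Pim2 rose by 4.52 ± 0.21 and the SOX factor gene Sox3 by 4.28 ± 0.20. The member that fell was the N-cadherin gene Cdh2 (-1.84), whose call was lost without any 1 of the arrays compared (adjusted p from 0.093 to 0.16). Otx2, a factor of the epiblast and anterior neural tissue, rose by 2.53 ± 0.30, a call lost without ESC replicate 1 (adjusted p = 0.056) and without EpiLC replicate 1 (adjusted p = 0.051). Of 14 core pluripotency genes 2 rose and 1 fell, with the same counts adjusted over the list alone and no call of the list (camera adjusted p = 0.4). Utf1 rose by 2.01 ± 0.16 and Lin28a by 1.74 ± 0.29, while Sox2 fell by 2.19 ± 0.26. The call of Lin28a was lost without any 1 of the arrays compared (adjusted p from 0.055 to 0.12), and those of Sox2 and of Zfp42 (-1.93 ± 0.22), a marker of naive cells, were lost without ESC replicate 1 (adjusted p = 0.067 and 0.063) and without ESC replicate 2 (adjusted p = 0.057 and 0.054).

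Genes of germ cell specification were lower in EpiLC, with 3 of 22 higher and 10 lower, or 3 and 12 adjusted over the list alone (camera adjusted p = 0.00051, adjusted p = 0.33 with an estimated correlation). The list shares Prdm14 and Nanog with the naive list. Lin28a was 1 of those that rose, and the others, Rhox5 (2.26) and the testis kinase gene Stk31 (1.39), were chosen after their values were seen. The receptor genes Kit and Lifr fell by 3.46 ± 0.30 and 3.15 ± 0.19. Tfap2c and Prdm1, which encode transcription factors needed for germ cell fate, fell 13.5-fold and 5.66-fold, but these calls were lost without ESC replicate 1 (adjusted p = 0.051 and 0.055) and without ESC replicate 2 (adjusted p = 0.053 and 0.077). Dppa3 (stella) differed by -1.11 ± 0.31 and did not pass the test (adjusted p = 0.086). With the replicate block it was called lower (adjusted p = 0.043), as it was without EpiLC replicate 2 (adjusted p = 0.032), within a range of 0.021 to 0.33 over all settings tried. Of 25 genes of the later germline and meiosis 5 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.32 with an estimated correlation, and 0.053 with the filter on low values, in a range of 0.00072 to 0.32). The piRNA pathway gene Mael rose by 3.51 ± 0.25, and the ATP carrier gene Slc25a31 (3.09), the synaptonemal complex genes Sycp3 (2.93) and Sycp1 (2.04), and the helicase gene Ddx4 (1.77, chosen after its value was seen) were the others. Without ESC replicate 1 and without ESC replicate 2 the calls of Slc25a31 (adjusted p = 0.057 and 0.053), Sycp3 (0.11 and 0.081) and Sycp1 (0.097 and 0.11) were lost, and that of Sycp1 also without EpiLC replicate 1 (0.063) and EpiLC replicate 2 (0.076).

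Targets of FGF and ERK signalling were higher in EpiLC, induced with activin and bFGF, than in ESC, kept in 2i and LIF. The media differ in each of these, so the rise cannot be credited to bFGF alone. Of 15 members 7 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 6.2e-08, adjusted p = 0.11 with an estimated correlation). Egr1 rose by 6.02 ± 0.22 and Myc by 2.41 ± 0.23, and the ERK phosphatase gene Dusp4 by 2.34 ± 0.33, a call lost without ESC replicate 1 (adjusted p = 0.092) and ESC replicate 2 (adjusted p = 0.08). The stress and immediate early list, which shares Egr1 and Fos with it, had 5 of 20 members higher and 0 lower, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.00091, adjusted p = 0.16 with an estimated correlation, and 0.11 with the filter on low values, in a range of 0.00032 to 0.16). Its largest change after Egr1 was that of the growth arrest gene Gadd45g (4.35 ± 0.27). Fos itself (1.68) was named after its value was seen. Targets of BMP signalling had 0 members higher and 2 of 14 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.35), namely Id4 (-5.30 ± 0.26) and Gata2 (-3.50 ± 0.19). Among 11 activin and Nodal targets 1 rose and 2 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.96). Skil, an inhibitor of SMAD signalling, rose by 2.03 ± 0.23, and the Nodal antagonist gene Lefty2 fell by 2.91 ± 0.20. The homeobox gene Gsc fell by at least 2.26, a call lost without ESC replicate 1 (adjusted p = 0.1), without ESC replicate 2 (adjusted p = 0.09) and after compression of low values.

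Among the lists of other lineages, only Hox genes were called as a set in this step. The Hox list was called down (camera adjusted p = 0.032, adjusted p = 0.28 with an estimated correlation), although only 2 of its 33 members fell and 0 rose, with the same counts adjusted over the list alone. These were Hoxc4, which fell by at least 4.07, and Hoxc10, which fell by at least 1.78, a call lost without ESC replicate 1 (adjusted p = 0.072), ESC replicate 2 (0.1) and EpiLC replicate 2 (0.051) and after compression of low values. The call of the list was lost with the replicate block (adjusted p = 0.051), without EpiLC replicate 1 (0.19) and with the filter on low values (0.59), within a range of 0.0049 to 0.59. Other lineage lists were not called (camera adjusted p = 0.27 for primitive streak and mesoderm, 0.22 for endoderm, 0.35 for neuroectoderm, 0.51 for trophoblast, 0.66 for blood and endothelium and 0.25 for the 2-cell-like state). The 2-cell-like list was called higher with every probe set tested (adjusted p = 0.046, in a range of 0.046 to 0.69). In the primitive streak and mesoderm list, with a median of 0 and a mean of -0.46, 0 genes rose and 4 of 24 fell, or 5 adjusted over the list alone, among them the caudal homeobox gene Cdx1 (-4.19 ± 0.32) and Gata2. In the neuroectoderm list 3 of 17 rose and 1 fell, or 3 and 2 adjusted over the list alone, with the neuronal factor gene Neurod1 higher by 3.34 ± 0.34 and the tubulin regulator gene Stmn2 lower by 2.43 ± 0.21. Counts of genes higher and lower were 3 and 0 of 18 in endoderm, 0 and 2 of 13 in trophoblast, 1 and 0 of 17 in blood and endothelium, and 2 and 1 of 6 in the 2-cell-like list. Adjusted over the list alone, they were the same except for trophoblast, with 3 lower.

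Lists of epigenetic and metabolic genes were not called in limma's camera, although most of them had called members. In the DNA methylation list 3 of 22 genes rose and 1 fell, with the same counts adjusted over the list alone and with Dnmt3a and Dnmt3b leading. Its median (-0.32) and its mean (0.05) differed in sign, and camera's direction was down (adjusted p = 0.74). In the list of histone H3 lysine 9 and 27 methylation 0 genes rose and 4 of 34 fell, also adjusted over the list alone, with a median of 0.07, a mean of -0.16 and a downward test (camera adjusted p = 0.63). In glycolysis 1 of 18 rose and 3 fell, or 1 and 4 adjusted over the list alone. The lactate exporter gene Slc16a3 rose by 3.54 ± 0.42, a call lost without EpiLC replicate 1 (adjusted p = 0.056). Counts were 0 and 0 of 36 for oxidative phosphorylation in limma (0 and 3 at an unadjusted p under 0.05), 1 and 0 of 33 for the cell cycle, 1 and 1 of 12 for cell cycle inhibitors, and 4 and 2 of 27 for imprinted genes, and the counts adjusted over the list alone were the same. The camera adjusted p was 0.27 for glycolysis, 0.22 for oxidative phosphorylation, 0.51 for the cell cycle, 0.3 for its inhibitors, 0.25 for imprinted genes and 0.3 for epithelial and mesenchymal genes. With every probe set tested the imprinted list was called higher (adjusted p = 0.015, in a range of 0.015 to 0.47). The cyclin-dependent kinase inhibitor gene Cdkn1c, which is imprinted, rose by 2.84 ± 0.22. Ndn (1.38) and Impact (-1.02) among imprinted genes and the claudin gene Cldn7 (1.57) among epithelial genes were chosen after their values were seen. Of 20 epithelial and mesenchymal genes 2 rose and 3 fell, or 3 and 3 adjusted over the list alone. The epithelial splicing regulator gene Esrp1 rose by 2.85 ± 0.23, while the fibronectin gene Fn1 and the vimentin gene Vim fell by 2.52 ± 0.18 and 2.14 ± 0.15.

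**Figure D2:**
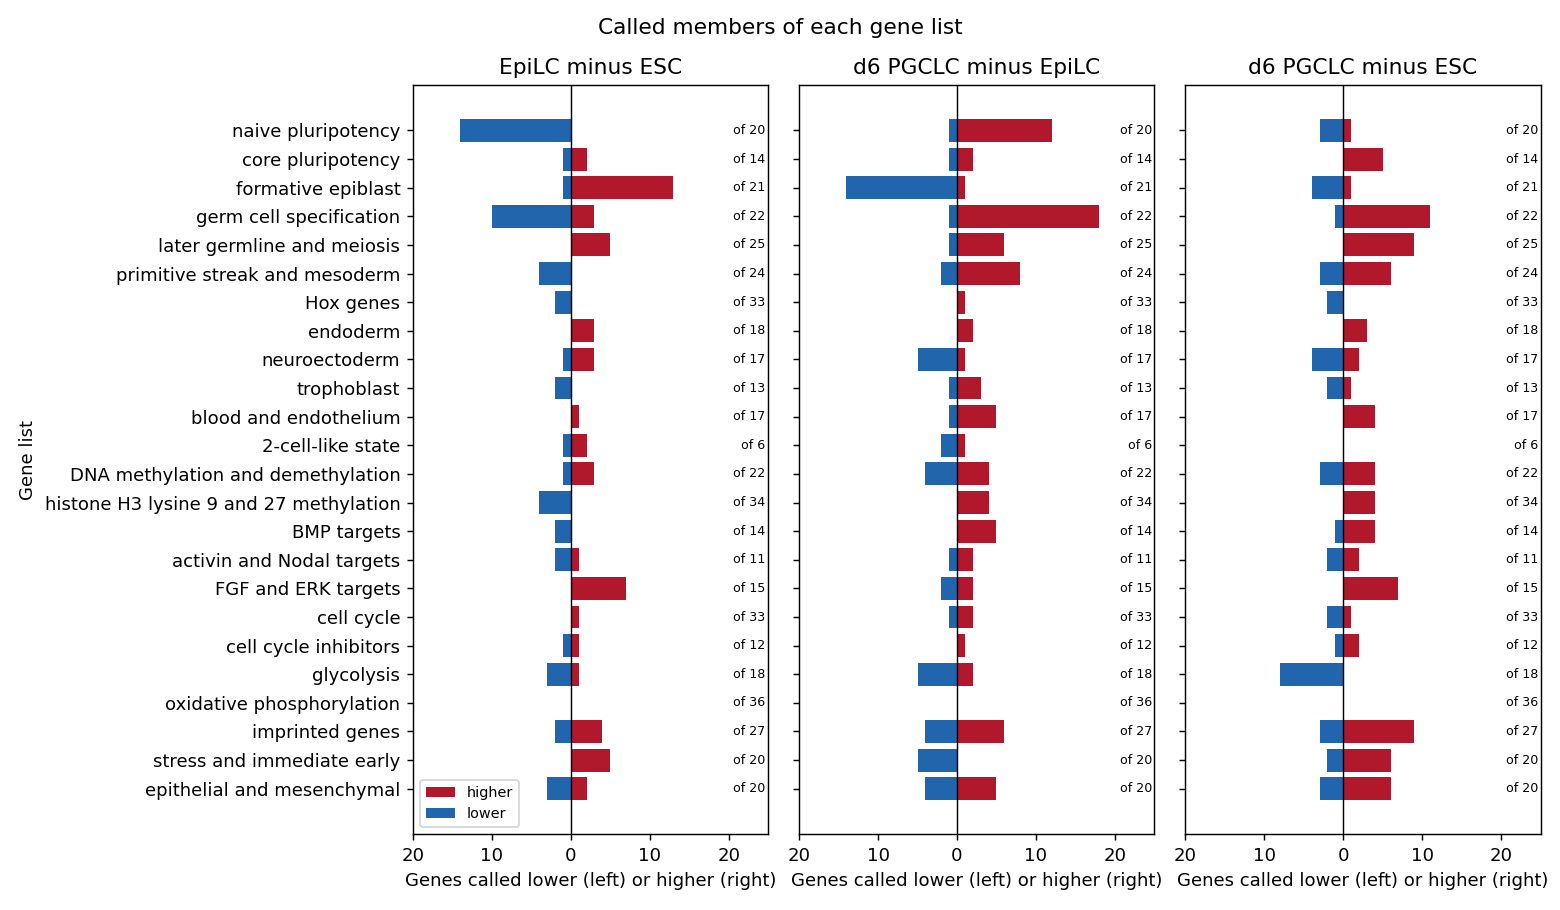
Number of genes called lower (left of 0) and higher (right of 0) in each of the 24 lists (vertical axis) for each of the 3 comparisons, with the number of measured members at the right edge. The longest bar is that of germ cell specification in PGCLC against EpiLC (18 higher of 22), followed by naive pluripotency in EpiLC against ESC (14 lower of 20) and formative epiblast in PGCLC against EpiLC (14 lower of 21).

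From EpiLC to PGCLC, the genes that specify germ cells rose and those of the formative epiblast fell. Prdm14 rose by at least 7.65 (adjusted p = 0.00019), from 3.08 ± 0.34 in EpiLC to 10.96 ± 0.11 in PGCLC (SD, n = 2 each), Tfap2c by 5.46 ± 0.39, Prdm1 by 4.98 ± 0.32 and Dppa3 by 3.79 ± 0.31. Prdm1 and Dppa3 are also the genes that drive the reporters in these cells, and whether their probe sets read reporter transcripts is not given in the sources used here. Nanog and Sox2 rose by 2.60 ± 0.21 and 2.02 ± 0.26. Pou3f1 fell by 6.24 ± 0.30 (75.8-fold, adjusted p = 0.00036), Dnmt3b fell by 5.11 ± 0.26, Otx2 fell by 4.70 ± 0.30 and Fgf5 fell by 4.50 ± 0.32. Pou5f1 differed by 0.10 ± 0.15 (adjusted p = 0.71).

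This step had more called genes than the first, 1298 higher and 998 lower, or 12.6% of those tested, although the difference in number was not tested. Besides Prdm14, the increases taken by the same rule were those of the metalloprotease gene Mep1b (at least 5.64), BC048679 (6.87), the apelin receptor gene Aplnr (at least 6.29), the actin-bundling gene Lcp1 (6.61), Gm9112 (at least 5.42), Glis3 (at least 5.72) and the protein kinase C gene Prkch (6.44). The decreases included those of Slc16a3 (at least 7.05), the carbonyl reductase gene Cbr3 (-6.49), Tmem54 (at least 6.4), Pou3f1, Ppp1r1a (-5.72) and Fgf4 (-5.44). All 2296 called genes had the same sign within both replicate numbers, again nearly ensured by the rule for a call. Leaving out arrays gave 790 higher and 521 lower without EpiLC replicate 1, 799 and 606 without EpiLC replicate 2, 651 and 648 without PGCLC replicate 1, and 545 and 477 without PGCLC replicate 2, and the filter on low values left 643 lower.

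Of 22 germ cell specification genes 18 rose and 1 fell, or 19 and 1 adjusted over the list alone (camera adjusted p = 5.4e-14, adjusted p = 0.14 with an estimated correlation). Besides the factors above, the integrin gene Itgb3 rose by at least 5.86 and the X-linked homeobox gene Rhox6 by 5.65 ± 0.56. The member that fell was Lin28a (-2.20 ± 0.29), whose product binds let-7 precursors. In the naive list 12 of 20 genes rose and 1 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 7.7e-07, adjusted p = 0.12 with an estimated correlation). Tcl1 rose by 5.24 ± 0.31 and Nr5a2 by 4.97 ± 0.23, and Fgf4 was the member that fell. Zfp42 rose by 1.40 ± 0.22, a call lost without EpiLC replicate 2 (adjusted p = 0.064) and PGCLC replicate 1 (0.055). Klf4 differed by 1.11 ± 0.29 and did not pass the test (adjusted p = 0.053), but was called higher with the replicate block (adjusted p = 0.029, in a range of 0.029 to 0.19 over the settings tried). The formative list had 1 of 21 members higher and 14 lower, also adjusted over the list alone (camera adjusted p = 1.5e-11, adjusted p = 0.11 with an estimated correlation), with Pim2 at -5.13 and Sall2 at -4.88. The member that rose, the WNT antagonist gene Dkk1 (1.98), was chosen after its value was seen. In the core list 2 of 14 rose and 1 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.61). Of 25 later germline genes 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.53), and the meiotic cohesin gene Smc1b rose by 3.51 ± 0.34.

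Mesodermal genes and BMP targets also rose in PGCLC, which were cultured with BMP4 and BMP8a. Of 24 primitive streak and mesoderm genes 8 rose and 2 fell, or 9 and 3 adjusted over the list alone. The list had a camera adjusted p of 0.008, 0.31 with an estimated correlation and 0.49 with the filter on low values. Over all settings its adjusted p ran from 0.0014 in fry to 0.57 in camera. Gata2 rose by 6.34 ± 0.19, the LIM homeobox gene Lhx1 by at least 4.82 and the BMP target gene Msx2 by 4.13 ± 0.27. The list of 14 BMP targets had a camera adjusted p of 0.0032, 0.21 with an estimated correlation and 0.071 with the filter on low values. Over all settings its adjusted p ran from 0.00069 in fry to 0.21 in camera. Of its members 5 rose and 0 fell, also adjusted over the list alone. The members were Gata2, Msx2, Id3 (2.96), Smad6 (2.54) and Id4 (1.32, chosen after its value was seen), but the calls of Id3 and Smad6 were lost without PGCLC replicate 1 (adjusted p = 0.066 and 0.1) and PGCLC replicate 2 (0.065 and 0.13), and that of Smad6 also without ESC replicate 1 (0.07) and ESC replicate 2 (0.071). Endothelial markers moved in the same arrays. Emcn, an endothelial surface glycoprotein gene, rose by 4.59 ± 0.26, the tyrosine kinase receptor gene Tie1 by at least 3.86 and the VE-cadherin gene Cdh5 by 4.91 ± 0.66. In the list of blood and endothelium as a whole 5 of 17 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.33). The mesodermal genes called lower were Mixl1 (at least 1.52) and Eomes, which fell 2-fold (adjusted p = 0.033), a call lost whichever array was left out (adjusted p from 0.069 to 0.17). Mixl1, Kdr (1.53) and Lmo2 (-1.57) were chosen after their values were seen.

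Neural genes tended the other way without a call of the list. Of 17 neuroectoderm genes 1 rose and 5 fell, also adjusted over the list alone, with Pax6 (2.55), a gene of neural and eye development, as the 1 that rose, chosen after its value was seen. The test missed its threshold (camera adjusted p = 0.053), which it passed without EpiLC replicate 1 (adjusted p = 0.03), with the filter on low values (0.01), with the mean of a gene's probe sets (0.024) and with every probe set tested (0.0046), within a range of 0.0046 to 0.31. Neurod1 fell by 3.50 ± 0.34, the oligodendrocyte lineage gene Olig2 by 2.68 ± 0.38 and the neuronal tubulin gene Tubb3 by 2.60 ± 0.32. The counts higher and lower were 3 and 1 of 13 in trophoblast, 2 and 0 of 18 in endoderm, 1 and 0 of 33 among Hox genes and 1 and 2 of 6 in the 2-cell-like list. Adjusted over the list alone they were the same, except for 3 and 2 in trophoblast and 0 and 0 among Hox genes, and the camera adjusted p was 0.53, 0.38, 0.46 and 0.3. The 2-cell-like list was called lower with every probe set tested (adjusted p = 0.044, in a range of 0.044 to 0.9). The placental gene Plac1 rose by 3.84 ± 0.34. Of 15 FGF and ERK targets 2 rose and 2 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.68), with Myc at -2.51 ± 0.23 and Egr1 at -2.22 ± 0.22. Among activin and Nodal targets 2 of 11 rose and 1 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.53). In the stress list 0 of 20 genes rose and 5 fell, or 2 and 5 adjusted over the list alone, with Atf3 at -2.86 ± 0.27 and the heat shock gene Hspa1a (-1.28, chosen after its value was seen), and its median (0.02) and mean (-0.45) differed in sign under a downward test (camera adjusted p = 0.25).

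Glycolytic genes and de novo methyltransferase genes were lower in PGCLC. In glycolysis 2 of 18 genes rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.23 with an estimated correlation). The lactate dehydrogenase gene Ldha fell by 3.99 ± 0.23, from 13.23 ± 0.14 to 9.25 ± 0.43 (SD, n = 2 each), and the phosphofructokinase gene Pfkl fell by 3.38 ± 0.47. Tpi1 (-1.87), the glucose transporter gene Slc2a1 (-1.25) and the hexokinase gene Hk1 (2.46) completed these counts and were chosen after their values were seen. The platelet isoform gene Pfkp instead rose by 2.80 ± 0.20, a call lost with the mean of its probe sets. No gene of 36 in oxidative phosphorylation was called in limma, also adjusted over the list alone (camera adjusted p = 0.6), with 0 higher and 2 lower at an unadjusted p under 0.05, and Ndufa5 differed by -0.75 ± 0.63 (adjusted p = 0.5). In the DNA methylation list 4 of 22 genes rose and 4 fell, or 5 and 4 adjusted over the list alone. Its median was 0.41, its mean -0.27 and camera's direction up (adjusted p = 0.6). Dnmt3b, Dnmt3a (-4.07 ± 0.17) and their cofactor gene Dnmt3l (-3.83 ± 0.26) fell. The genes that rose, Smug1 (1.69), Uhrf2 (1.64), Mbd1 (1.20) and Mbd2 (1.19), were chosen after their values were seen. Uhrf1, whose product is needed for maintenance methylation, fell by 2.67 ± 0.64 (adjusted p = 0.041 in limma). The call was lost whichever array was left out, in fits that held no replicate block. With the low-value filter and the replicate block together, its adjusted p in limma was 0.00017. In the list of histone H3 lysine 9 and 27 methylation 4 of 34 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.53), with the lysine 9 demethylase genes Kdm3a (1.71) and Kdm3b (1.49) among them. The call of Kdm3a was lost without EpiLC replicate 1 (adjusted p = 0.07), EpiLC replicate 2 (0.059) and PGCLC replicate 2 (0.065), and that of Kdm3b without PGCLC replicate 2 (0.051).

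Imprinted genes changed in both directions, with 6 of 27 higher and 4 lower, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.3). Plagl1 rose by 5.16 ± 0.46 and the ankyrin repeat gene Asb4 by 3.39 ± 0.30, while the neuronatin gene Nnat fell 16-fold. Mirg (-3.02), Grb10 (-2.14) and Meg3 (-1.95) also fell and were chosen after their values were seen. In the cell cycle list 2 of 33 rose and 1 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.7), with the cyclin D1 gene Ccnd1 lower by 2.95 ± 0.17. Of 12 cell cycle inhibitor genes 1 rose and 0 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.3, but called at 0.05 without EpiLC replicate 1, in a range of 0.05 to 0.59). Of 20 epithelial and mesenchymal genes 5 rose and 4 fell, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.3), among them the collagen gene Col3a1 (2.54 ± 0.27) and the tight junction gene Ocln (lower by at least 4.1). In the same counts Fn1 (1.89), Vim (1.72), Cldn4 (-1.98), Twist1 (-1.57) and the E-cadherin gene Cdh1 (-1.22) were chosen after their values were seen.

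**Figure D3:**
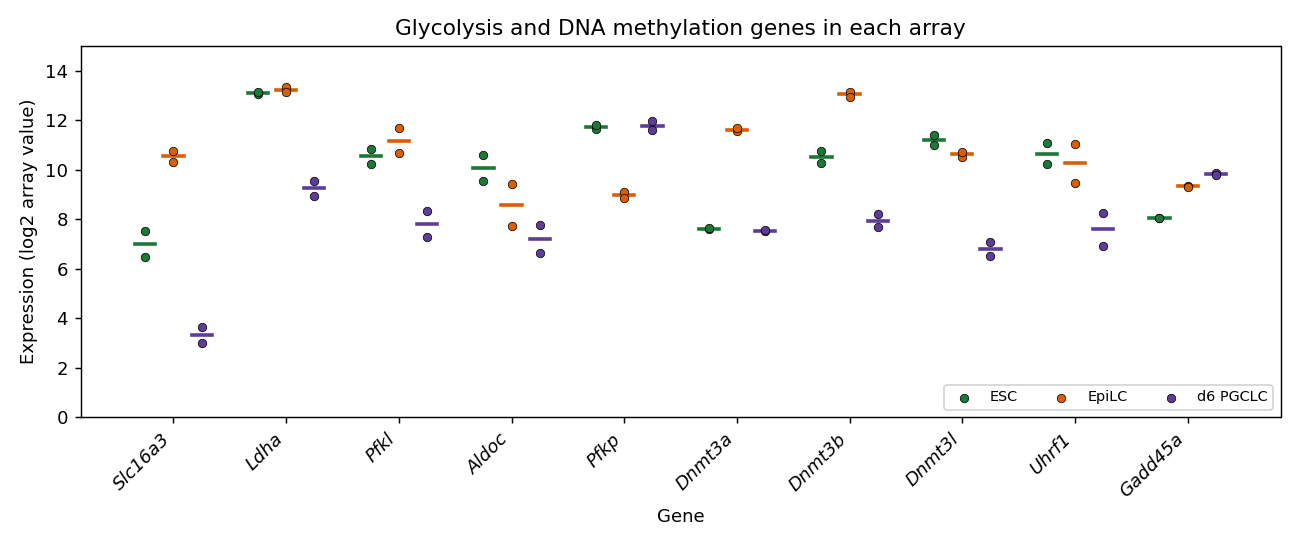
Log2 array values (vertical axis) of 5 glycolysis and 5 DNA methylation genes (horizontal axis), with 1 point per array, a bar at the mean of each group and colours for ESC, EpiLC and PGCLC. Ldha lies near 13 in ESC and EpiLC and at 9.25 in PGCLC, and Dnmt3a is at 11.61 in EpiLC and under 8 in both other groups.

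The last comparison set PGCLC against the ESC from which the path began. Germ cell and later germline genes were called higher in PGCLC (11 of 22 and 9 of 25 members) and glycolytic genes lower (8 of 18). These list calls were lost with an estimated correlation (adjusted p = 0.25, 0.25 and 0.15). The pluripotency genes Nanog (-0.46 ± 0.21, adjusted p = 0.24), Sox2 (-0.17 ± 0.26, adjusted p = 0.78) and Pou5f1 (0.04 ± 0.15, adjusted p = 0.93) were not called. Dppa3 rose by 2.68 ± 0.31 (6.39-fold, adjusted p = 0.0039), the homeobox genes Rhox9 and Rhox6 by 5.63 ± 0.41 and 5.58 ± 0.56, and the germ cell survival gene Dnd1 by 3.70 ± 0.21. Klf4 fell by 4.06 ± 0.29 and Fgf4 fell by 6.11 ± 0.37 (69.3-fold, adjusted p = 0.00066). Prdm14 (1.10 ± 0.23), Tfap2c (1.71 ± 0.39) and Prdm1 (2.48 ± 0.32) were also higher. The calls of Prdm14 and Tfap2c were lost without any 1 of the arrays compared (adjusted p from 0.11 to 0.18 and from 0.14 to 0.19), and that of Prdm1 without ESC replicate 1 (adjusted p = 0.06).

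There were 1043 genes called higher and 925 lower in PGCLC than in ESC, 10.8% of those tested. All 1968 had the same sign within both replicate numbers, which the rule for a call nearly ensures. The differences taken by the same rule included those of Prkch (at least 6.76), the transcription factor gene Ets1 (at least 6.16), Aplnr (at least 6.22), BC048679 (6.34), the iron exporter gene Slc40a1 (5.99), the laminin gene Lama4 (at least 4.88) and the RNA-binding protein gene Rbm46 (at least 5.03) upwards, and of the thyrotropin-releasing hormone gene Trh (-6.12), Sp5 (-6.12), Fgf4, the homeobox gene Nkx1-2 (-5.99), Dnah8 (-5.83) and Cbr3 (-5.72) downwards. Without ESC replicate 1 the calls of Lama4 (adjusted p = 0.063) and Nkx1-2 (adjusted p = 0.059) were lost. Without ESC replicate 1 the counts were 333 higher and 297 lower, without ESC replicate 2 395 and 338, without PGCLC replicate 1 483 and 568, and without PGCLC replicate 2 482 and 498. The filter on low values left 695 higher.

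The germ cell specification list had 11 of 22 members higher and 1 lower, also adjusted over the list alone (camera adjusted p = 3.3e-06, adjusted p = 0.25 with an estimated correlation), with Itgb3 up by 4.96 ± 0.32. The member that fell, Lifr (-1.06), was chosen after its value was seen. Of 25 later germline genes 9 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00064, adjusted p = 0.25 with an estimated correlation, and 0.064 with the low-value filter and the replicate block together, in a range of 9.2e-05 to 0.25). Slc25a31 rose by 4.40 ± 0.34, Smc1b by 3.82 ± 0.34, the piRNA pathway gene Piwil2 by 3.19 ± 0.36 and Ddx4 by 2.95 ± 0.21, from a level of 7.04 ± 0.22 in ESC (SD, n = 2). The naive list stayed below its ESC level, with 1 of 20 higher and 3 lower, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.00013, adjusted p = 0.15 with an estimated correlation). The genes that fell were Klf4, Fgf4 and Tbx3 (-3.19 ± 0.22). Of 14 core genes 5 rose and 0 fell, or 5 and 1 adjusted over the list alone, with Utf1 at 1.69 and Sall4 (1.03, chosen after its value was seen). The list was not called (camera adjusted p = 0.21), except in some alternatives, such as with every probe set tested (0.034). Over the settings tried its adjusted p ran from 0.024 in fry to 0.38 in camera. Of 21 formative genes 1 rose and 4 fell, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.2), with Foxd3 (lower by at least 3.45) and Dnmt3b (-2.59 ± 0.26) among those that fell, as was Sall2 (-1.67, chosen after its value was seen).

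FGF and ERK targets were higher in PGCLC than in ESC, the cells kept in 2i. Of 15 members 7 were up and 0 down, also adjusted over the list alone (camera adjusted p = 3.3e-06, adjusted p = 0.15 with an estimated correlation). Dusp4 rose by 3.88 ± 0.33 and Egr1 by 3.80 ± 0.22. Of 20 stress and immediate early genes 6 rose and 2 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.21), with Jun up 7.97-fold. The genes that fell, Trib3 (-1.59) and Atf3 (-1.10), were chosen after their values were seen, as was Id3 (2.02) among BMP targets. The BMP list had 4 of 14 higher and 1 lower, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.058), with Msx2 at 5.12 ± 0.27 and Id4 at -3.98 ± 0.26. That list was called higher in camera with only the groups compared (adjusted p = 0.018), with median centring (0.041) and with compression of low values (0.039). It was also called higher without ESC replicate 1, EpiLC replicate 1 or EpiLC replicate 2. Over the settings tried its adjusted p ran from 0.0038 in fry to 0.25 in camera. Of 11 activin and Nodal targets 2 rose and 2 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.33).

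Among lineage lists only endoderm was called, with 3 of 18 genes higher and 0 lower, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.03, adjusted p = 0.25 with an estimated correlation). This call was lost with the filter on low values (camera adjusted p = 0.061), with the mean of a gene's probe sets (0.078) and without ESC replicate 2. Over the settings tried the list had an adjusted p from 0.0038 in fry to 0.25 in camera. Its leading member was the basement membrane collagen gene Col4a1 (3.11 ± 0.29), which many cell types express. In the mesoderm list 6 of 24 rose and 3 fell, or 8 and 3 adjusted over the list alone, with Lhx1 higher by at least 4.78. The camera adjusted p was 0.079, but the list was called with every probe set tested (0.048) and without ESC replicate 1. Over the settings tried its adjusted p ran from 0.0038 in fry to 0.64 in camera. In blood and endothelium 4 of 17 rose and 0 fell, or 5 and 0 adjusted over the list alone. The camera adjusted p was 0.091, and 0.049 with the mean of a gene's probe sets. Over the settings tried the list had an adjusted p from 0.0038 in fry to 0.33 in camera. Tie1 was higher by at least 4.02 and Emcn by 4.72 ± 0.26. Counts higher and lower were 2 and 4 of 17 in neuroectoderm, 1 and 2 of 13 in trophoblast, 0 and 2 of 33 among Hox genes and 0 and 0 of 6 in the 2-cell-like list in limma, and 3 and 4, 3 and 2, 0 and 2, and 0 and 0 adjusted over the list alone. The camera adjusted p was 0.3 for neuroectoderm, 0.24 for Hox genes and 0.87 for the 2-cell-like state, where 0 genes were higher or lower at an unadjusted p under 0.05. Cdx1 (-2.04) among mesodermal genes and Tubb3 (-1.86) and Map2 (1.79) among neural genes were chosen after their values were seen. The median of the trophoblast list (-0.24) was opposite in sign to its mean (0.38) and to the upward test (camera adjusted p = 1).

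The glycolysis list was lower in PGCLC than in ESC, with 0 of 18 genes up and 8 down, also adjusted over the list alone (camera adjusted p = 3.3e-06, adjusted p = 0.15 with an estimated correlation). Ldha fell by 3.85 ± 0.23 and Slc16a3 fell by at least 3.51. The oxidative phosphorylation list had 0 of 36 genes called in limma, also adjusted over the list alone, with 0 higher and 3 lower at an unadjusted p under 0.05, and a median of -0.21 (camera adjusted p = 0.058). It was called lower with the replicate block (adjusted p = 0.0062), without PGCLC replicate 1 (0.0042), with median centring (0.043), with the mean of a gene's probe sets (0.047) and with every probe set tested (0.025), in a range of 0.0042 to 0.41. The imprinted list had 9 of 27 genes higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.058). It was called higher with median centring (camera adjusted p = 0.043), without ESC replicate 1 and without PGCLC replicate 1. Over the settings tried its adjusted p ran from 0.0028 in fry to 0.25 in camera. The growth factor gene Igf2 rose by 4.47 ± 0.23 and Cdkn1c by 3.66 ± 0.22. Dnmt3l fell by 4.43 ± 0.26 and the DNA damage response gene Gadd45a rose by 1.77 ± 0.17 in the DNA methylation list, where 4 of 22 rose and 3 fell, also adjusted over the list alone. Uhrf2 (1.61), Mbd3 (1.35) and Mbd1 (1.24) in that list, and the imprinted RNA genes Mirg (-2.51) and Meg3 (-2.29), were chosen after their values were seen.

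None of the remaining lists of this comparison was called in limma's camera. The median and mean were 0.10 and -0.22 for DNA methylation, with camera's direction up (adjusted p = 0.92), and -0.19 and 0.01 for histone H3 lysine 9 and 27 methylation, with its direction down (adjusted p = 0.74). They were 0.03 and -0.02 for the cell cycle, with its direction up (adjusted p = 0.86), and -0.15 and 0.07 for cell cycle inhibitors, with its direction down (adjusted p = 1). The counts higher and lower in the last 3 were 4 and 0 of 34, 1 and 2 of 33, and 2 and 1 of 12, or 4 and 0, 1 and 2, and 2 and 3 adjusted over the list alone. The cyclin D1 gene Ccnd1 fell by 3.11 ± 0.17. Of 20 epithelial and mesenchymal genes 6 rose and 3 fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.22), with Esrp1 and Col3a1 up by 3.78 ± 0.23 and 3.04 ± 0.27. Cldn4 (-1.97) and Cdh1 (-1.30) fell and were chosen after their values were seen.

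Many genes called in the first step moved back in the second. Of the 1543 genes called between ESC and EpiLC, 697 (45.2%) were called in the opposite direction between EpiLC and PGCLC. Tmem54, Pou3f1, Tmem59l, the proteoglycan gene Dcn and Pim2 rose and then fell, and Prdm14, Lrrc34, Tcl1, Plagl1 and Nr5a2 fell and then rose. Against ESC, PGCLC differed by -0.04 ± 0.25 in Lrrc34 and by 0.38 ± 0.30 in Pou3f1, neither of which was called. There were 342 genes higher then lower and 355 lower then higher, of which 274 and 286 were not called between PGCLC and ESC. Simulated unchanged groups shared 0, a figure that leaves out the effects. Independent lists would share 39.6 and 58.6 genes, but that figure ignores that both steps use the same 2 EpiLC arrays with opposite sign. Fold changes of both steps correlated at -0.49 across genes, no more than the -0.50 of simulated unchanged groups that shared those arrays, while their covariance was -0.46 against -0.09. The correlation does not depend on the size of the differences and cannot tell effects from noise. The covariance can, and the shared arrays of the simulation left a difference of -0.37 unaccounted for. Part of the reversals may still come from the shared arrays, and which genes these are cannot be told.

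Fewer genes kept their direction over both steps, 40 higher then higher and 34 lower then lower. Independent lists would share 51.5 and 45 genes, but that figure again ignores that EpiLC enters both steps with opposite sign. Slc40a1 rose by 3.82 ± 0.27 and then by 2.18 ± 0.27, and Stmn2 fell by 2.43 ± 0.21 and then by 2.40 ± 0.21. With the replicate block the second count was 65, and with the filter on low values 183 genes were higher then lower. Without ESC replicate 1 the counts were 96 higher then lower, 102 lower then higher, 11 higher then higher and 3 lower then lower, without ESC replicate 2 92, 97, 8 and 3, without EpiLC replicate 1 113, 199, 15 and 9, without EpiLC replicate 2 173, 237, 9 and 11, without PGCLC replicate 1 204, 211, 16 and 21, and without PGCLC replicate 2 167, 186, 15 and 16. In PGCLC 570 genes were higher than in both other groups and 419 were lower.

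**Figure D4:**
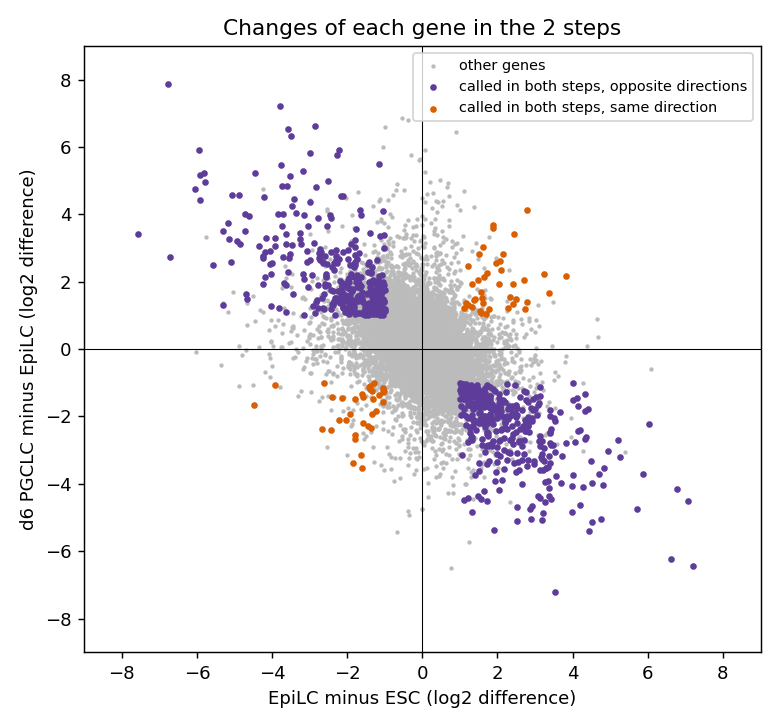
Log2 difference of each gene between EpiLC and ESC (horizontal axis) and between PGCLC and EpiLC (vertical axis), with genes called in both steps coloured by whether their directions were opposite or the same. The 697 genes called in opposite directions lie in the upper left and lower right, and the 40 and 34 genes called in the same direction lie in the upper right and lower left.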

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

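Compression of low values, and the low-value filter together with the replicate block, were chosen after the data were seen. Gene counts changed most when an array was left out, with the filter and with the minimum difference. Leaving out an array also lowers the residual degrees of freedom, so a lost call does not show that this array drove it. List calls depended most on the camera setting and on the kind of test. Camera with an estimated inter-gene correlation weakened 19 list results, and fry made 22 stronger. The estimate lay above the preset of 0.01 for germ cell specification (0.109), later germline (0.059), mesoderm (0.042) and FGF and ERK targets (0.027). It lay below 0.01 for the other lists that lost calls, such as naive pluripotency (-0.04), formative epiblast (-0.034) and glycolysis (0.001). In those lists a higher correlation cannot be why calls were lost. With an estimated correlation camera uses the 3 residual degrees of freedom, and with the preset about as many as there are genes. At 3 few lists can pass, so such a lost call says little about that list. No called gene or list among the 323 gene and 72 list results reversed under any setting that was run. Leaving out an array gave 156 to 560 genes higher and 181 to 670 lower in EpiLC than in ESC, 545 to 935 and 477 to 721 in PGCLC than in EpiLC, and 333 to 980 and 297 to 871 in PGCLC than in ESC. Over both steps it gave 8 to 16 genes higher then higher, 92 to 204 higher then lower, 97 to 237 lower then higher and 3 to 21 lower then lower, and 6 to 7, 6 to 8 and 5 to 9 lists past the threshold in the order of the comparisons. The lone sample left in a group was assumed to vary like the other groups. Of the gene results 87 were weaker without ESC replicate 1, 85 without ESC replicate 2, 50 without EpiLC replicate 1, 45 without EpiLC replicate 2, 49 without PGCLC replicate 1 and 62 without PGCLC replicate 2.

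With the filter on low values 446 genes were higher in EpiLC than in ESC and 4 lists were called there, 643 genes were lower in PGCLC than in EpiLC, 695 were higher in PGCLC than in ESC, and 183 were higher then lower over both steps. The filter with the replicate block gave 225 genes higher then lower and 4 lists called in EpiLC against ESC. A minimum log2 difference of 2 left 326 genes higher and 345 lower, 462 and 434, and 435 and 423 in the 3 comparisons, and 8 higher then higher, 132 higher then lower, 105 lower then higher and 4 lower then lower. The mean of a gene's probe sets gave 23 genes higher then higher, no mean-variance trend gave 22 lower then lower, and a fit of only the 2 groups gave 26 higher then higher, 232 lower then higher and 20 lower then lower. The replicate block gave more calls, 950 genes higher and 1113 lower, 1584 and 1242, and 1272 and 1126 in the 3 comparisons. Over both steps it gave 58 higher then higher, 463 higher then lower, 507 lower then higher and 65 lower then lower. It made 2 gene results stronger, and weakened 1 list and strengthened 1, with no other change of call among these results. With an estimated inter-gene correlation 0, 0 and 0 lists were called, where fry called 13, 13 and 15. The gap between the lowest correlation within groups and the highest between them was 0.026 and became 0.033 with compression. Compression weakened 26 gene results, the mean of probe sets 40, a minimum of 2 65, quantile normalization 6 and median centring 1. Testing every probe set made 7 list results stronger. The added constants planned for linear values were not run, because the values were already log2, and the planned comparison with another deposited table was not run, because its columns are named for samples not analysed here.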

Other observations

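The odds ratio of X-linked genes, the exact intervals of the shares of lists and the reading of the shares by those intervals were tests chosen after the results were seen, as were the genes named in this part. Several genes outside the lists of the report moved strongly. Epha4, an ephrin receptor gene, fell by at least 4.73 from ESC to EpiLC and rose by at least 4.24 from EpiLC to PGCLC, and the ERK phosphatase gene Dusp5 was higher in PGCLC than in ESC by at least 4.24. The surface glycoprotein gene Thy1 fell by 3.65 ± 0.33 from EpiLC to PGCLC, while the matrix protein gene Postn rose by at least 2.39. In a mesenchymal list of 15 measured genes that holds Thy1 and Postn, 2 rose and 2 fell in each of the steps, and 2 rose and 0 fell between ESC and PGCLC, with 4 higher at an unadjusted p under 0.05.

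Endothelial markers were high in PGCLC, with Cdh5, Tie1 and Emcn at 8.39, 7.36 and 8.45. Blood cells in these samples were argued against, since 0 of 14 erythroid and myeloid genes were called higher than in EpiLC in limma (0%, with an upper exact limit of 23.2%, and 2 higher at an unadjusted p under 0.05) and the abundant myeloid gene Lyz2 stood at 5.47 in EpiLC and 5.32 in PGCLC. Endothelial cells stayed open, since 8 of 19 further endothelial genes were called higher (42.1%, exact interval 20.3 to 66.5%), among them Icam2 (at least 4.21), Esam (3.87), Erg (at least 2.8), Robo4 (2.48) and Cldn5 (2.34), while Egfl7 (-0.62) and Eng (0.28) were not called. In that list 5 of the 19 genes had a mean of at least 7 in ESC, such as Egfl7 at 9.37, and 10 were higher and 1 lower in PGCLC than in ESC. Expression of these genes in the induced cells themselves was not tested, and the labels name no sort that would remove other cells.

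Targets of ERK and immediate early genes were high in EpiLC, with Egr1 at 10.23 against 4.2 in ESC. By the exact intervals, a reading chosen after the results were seen, no explanation was excluded by the lists drawn up for it. These lists left out genes of the report's lists except Ccnd1. For handling or dissociation of the cells 3 of 18 genes were called higher in EpiLC (16.7%, interval 3.6 to 41.4%), namely Zfp36 (1.67), Ccn1 (1.67) and Rhob (1.06). For a difference in ERK signalling between the culture conditions 1 of 16 was (6.2%, interval 0.2 to 30.2%), namely Shc4 (2.19), with 6 higher at an unadjusted p under 0.05, and 1 was called lower, Epha4 (by at least 4.73), the largest change in the list. Both shares lay under 25% of the list, the outcome set beforehand as speaking against each explanation. Both intervals, however, reached past that bound. The bFGF in the EpiLC medium and 2i in the ESC medium are part of the design, so the explanations cannot be told apart here.

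Replicates 1 and 2 differed alike in the 3 groups, with 98 of 8380 bright genes over 2-fold higher in replicate 1 of every group and 1 gene over 2-fold higher in replicate 2, and with the same sign in 54.9% of these genes against 25% by chance. The largest differences were those of Snord104, Atic, Lsm14b, Cdkn1b and Clasp2. A normalization error that follows brightness was argued against, because the largest absolute Spearman correlation of the replicate difference with mean level was 0.15. A difference of whole genes between cultures stayed open, because 2 probe sets of a gene shared the replicate difference with a correlation of 0.43, against 0.76 for EpiLC against ESC, a ratio of 0.56 (bootstrap interval 0.50 to 0.63), between the bounds set beforehand. A difference of single probe sets, as from amplification or labelling, was not tested.

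As a hypothesis tested on the data that raised it, X-linked genes may be called lower more often than autosomal genes from EpiLC to PGCLC, with an odds ratio of 2.11 (interval 1.40 to 3.09). Among bright genes 33 of 266 X-linked genes (12.4%) and 6.3% of 8099 autosomal genes were called lower (Fisher exact test, Benjamini-Hochberg p = 0.0019 over 6 tests), and with the replicate block 38 (14.3%) and 7.5% were, an odds ratio of 2.05. From ESC to PGCLC 11.3% and 6.3% were called lower (odds ratio 1.88, Fisher's exact test, Benjamini-Hochberg p = 0.0099). Examples were Pim2 (-5.13), the nucleotide synthesis gene Prps1 (-4.74), Eras (-4.43), Acsl4 (-4.19) and Sox3 (-4.10), and neighbouring members of a family such as Armcx1 and Armcx2 are not independent. The median difference of bright X-linked genes was 0.04 between EpiLC and PGCLC. Between PGCLC and ESC it was -0.08, within the range of -0.19 to 0.21 over the autosomes, which argued against a shift of all X-linked genes in that comparison. From EpiLC to PGCLC an autosome also stood out. On chromosome 16, 54 of 288 bright genes were called higher and 9 lower, with a median difference of 0.36. The odds ratio pools the autosomes, so it takes no account of such differences between chromosomes.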
